A study of Mus musculus with 48 samples.

How the data were processed

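Liver RNA from 48 male C57BL/6 mice aged 8 to 10 weeks was sequenced. Per the labels, 24 mice went through 1 advance of the light schedule by 6 h, a model of jet lag, and 24 mice stayed on a steady 12:12 light-dark cycle. Each arm holds 6 zeitgeber times (ZT, hours after lights-on), ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20, with 4 libraries per arm and time, which gives 12 groups. The treatment field of the labels reads the same for all 48 samples, so the arms were taken from the sample titles, which the column names of the deposited tables repeat. The design text of the series mentions ZT0 and ZT12 on day 7, whereas the sampling text describes collection at 4 h intervals between day 6 and day 7. The labels do not state whether ZT in the shifted arm is counted from the new lights-on, and times are used here as labelled. The serum metabolite data that the series mentions were not analysed here.

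The deposited count table holds raw counts per gene, as whole numbers, for 54532 mouse genes. The deposited FPKM table holds FPKM values, that is counts scaled by gene length and library, for the same genes and libraries. Per the labels, a sequencing company did the sequencing, mapping and quantification against mouse genome build mm10. The aligner and the counting program are not given in the sources used here. Tested on the values, each FPKM equalled the count divided by the gene length and by 1 factor per library, with a largest relative deviation of 5.3e-13% among genes with at least 100 counts. That factor was proportional to the median-ratio size factor of DESeq2, with a spread between libraries of 0%. All fits used the counts, and FPKM entered 1 alternative. Gene symbols, Ensembl identifiers, biotypes and coordinates are those of the deposited tables.

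Total counts ran from 15370303 to 19639753 per library. A count of 0 in a library allows up to 3 counts, which is 0.153 to 0.195 CPM (counts scaled to the library total), and this limit covers counting error alone. Libraries of the same group differed by more than counting error, with a mean chi-square per gene of 14.5 to 256 across the 72 pairs of libraries within groups.

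Differences between arms were tested with edgeR 4.0.16 in R 4.3.3. The filterByExpr rule on the 12 groups kept 14555 genes. TMM normalization, robust quasi-likelihood fits with 12 group means over all 48 libraries, and quasi-likelihood F tests gave a contrast at each of the 6 times and the mean of the 6 differences. Log2 fold changes are phase shift minus control. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. Daily rhythm was tested in a harmonic model with a mean, a cosine and a sine of 24 h per arm. The 2 rhythm terms were tested in each arm, and their differences between arms gave the test of differential rhythmicity. A test with 5 degrees of freedom for any difference of the time course between arms was run in the 12-group fit. With 1 cycle sampled, the period was fixed and not estimated.

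For 17 clock genes, harmonic curves were fitted by least squares to log2 CPM with a prior count of 2. Intervals are 95% intervals from 2000 bootstraps of libraries within groups, and p-values are from two-sided permutation tests with 100000 permutations of the arm labels within each time. The internal time of each library was the time, on a grid of 0.05 h, at which the control curves of the 17 genes matched it best. A control library was left out of the curves it was matched to. At a single time, 4 against 4 libraries were compared by a two-sided exact permutation test, which cannot give a p under 0.0286.

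Before the data were examined, 40 gene lists of pathways, liver functions and cell types were fixed, together with the tests and the rule for named genes. Of these, 39 had at least 3 members among the tested genes and 1 had too few. They were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, over 273 combinations of list and contrast. Which lists are described at which time was chosen from their results. Daily profiles of the lists were fitted to the mean of their standardised members, a test added later, as was the difference of list means in log2 CPM with each library left out. Genes named at single times are up to 5 higher and 5 lower with the largest fold change among called protein coding genes with a mean log2 CPM of at least 1, whose 4 libraries of 1 arm all lay above the 4 of the other arm. For the average difference the rule took up to 10 in each direction with the same sign at 5 or more times. For rhythm it took the 10 with the smallest p for a difference between arms and the 5 with the largest control amplitude, outside the activator and repressor lists of the core clock, which do not hold Dbp. From each list described, up to 4 members with the smallest p are named. All 17 clock genes belong to the named set. Other called genes, such as Cdc20 and Mki67 below the level limit, are named where a list holds them or where they were picked after their values were seen.

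Of 137 genes so selected, 61 overlap another annotated gene, and 10 of them overlap a gene with more than 10% of their own count. These 10 are Dbp, Per3, Nr1d1, mt-Atp8, mt-Nd6, Stab1, Sds, Acss2, Cdc20 and Ccna2.

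Alternatives planned beforehand were median-ratio size factors, no filter on low counts, a filter of CPM of at least 1 in at least 4 libraries, the replicate number as a block, limma trend on log2 of FPKM plus 0.1, DESeq2 1.42.0 Wald tests, fits to the 8 libraries of a time alone, a second harmonic, other sets of clock genes, other templates for internal time, an arm and time model without interaction, and leaving out each library. Replicate numbers do not pair libraries as far as the values show, since the correlation across genes of residuals in same-numbered pairs had a median of -0.0585 and exceeded 0.1 in 4 of 24 pairs. After the share of mitochondrial counts had been seen, a fit without the 8 libraries above 9.54% (the median plus 3 median absolute deviations) and a fit with the share as a covariate were added.

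The fits were tested on simulated data with the observed spread. At ZT8, 17 of 67 genes changed 1.5-fold, 51 of 67 changed 2-fold and 63 of 66 changed 4-fold were called, with 10 calls among 14355 unchanged genes. For the average over times these were 62 of 67, 66 of 67 and 66 of 66, with 5 calls among unchanged genes. Of genes given a peak 3 h later, 2 of 67 at a log2 amplitude of 0.25, 25 of 67 at 0.5 and 60 of 66 at 1 were called as differing in rhythm, with 4 false calls. In control, 47 of 134 rhythms of log2 amplitude 0.25 and 117 of 134 of amplitude 0.5 were called, with 14 calls among 14155 genes without rhythm. A shift of 3 h given to 66 genes was returned as 2.92 h. A list given a change was called with an adjusted p of 2.54e-15, or adjusted p = 2.61e-08 with an estimated correlation, and 0 of 38 unchanged lists were called. Genes were drawn independently of each other in the simulated data, and lists were made of random genes. The count of unchanged lists called therefore says nothing about real lists, whose members can vary together. Differences shared by many genes of a library, such as those with the mitochondrial share, were also absent, so false calls and power can differ in the real data. Mixed splits of the real livers, described below, gave up to 92 genes at ZT20, 46 at ZT0, 21 at ZT4, 2 at ZT8 and 0 at ZT12 and ZT16.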

Results

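Transcript levels in mouse liver were measured by RNA sequencing in 48 libraries, 24 from mice after a single 6 h advance of the light schedule and 24 from mice on a steady schedule. Each arm was sampled at 6 labelled times with 4 libraries per time. Total counts ran from 15370303 to 19639753 per library. Transcripts of the mitochondrial genome took a median of 7.11% of the counts, and 8 libraries exceeded 9.54%. In control these were ZT4 replicate 1 (11.5%), ZT8 replicate 2 (12.8%), ZT12 replicate 2 (15.1%) and ZT20 replicate 1 (12.1%). In the phase shift arm they were ZT0 replicate 1 (19.9%), ZT0 replicate 2 (9.88%), ZT4 replicate 2 (15.0%) and ZT4 replicate 3 (13.1%). Across libraries within groups, markers of Kupffer cells, the resident macrophages of the liver, had a slope of -2.73 log2 units (SE 0.24) per doubling of that share. Markers of sinusoidal endothelial cells had one of -2.15 (SE 0.19), and markers of stellate cells and fibroblasts one of 0 (SE 0.1).

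**Figure D1:**
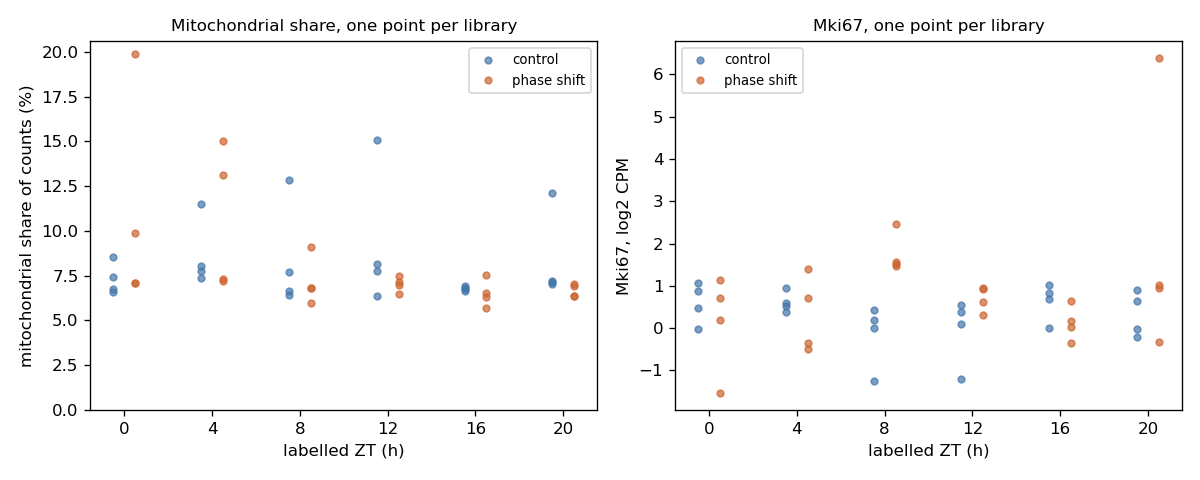
Mitochondrial share of counts in percent (left) and log2 CPM of Mki67 (right) against labelled ZT, 1 point per library, 24 libraries per arm. The highest mitochondrial share, 19.9%, is in phase shift ZT0 replicate 1, and Mki67 reaches 84 CPM in phase shift ZT20 replicate 2 against at most 5.39 CPM in the other 47 libraries.

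The first question was whether the liver clock of the advanced mice kept the same phase and amplitude as that of control mice 6 to 7 days after the advance. All 17 clock genes oscillated over the day in both arms. Arntl (Bmal1), the partner of CLOCK in the activating limb of the clock, had its fitted peak at ZT 22.4 in control and at ZT 22.0 after the shift, a difference of -0.40 h (95% interval -0.90 to 0.15, permutation p = 0.345, adjusted p = 0.533). Cry1, a repressor of CLOCK and BMAL1, peaked at ZT 19.5 and ZT 18.3, or -1.19 h (-1.90 to -0.50, permutation p = 0.0113, adjusted p = 0.192), the smallest p of the 17 genes. Dbp, a PAR bZIP factor under direct control of the clock, peaked at ZT 10.8 and ZT 9.91. Over the 17 genes the median difference was -0.47 h (-0.89 to 0, permutation p = 0.134), with 12 genes earlier and 5 later. This clock gene phase difference was -0.30 h without control ZT4 replicate 1, -0.28 h without control ZT4 replicate 3 and -0.23 h without the libraries with a high mitochondrial share.

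Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126 of mm10) stood at 31.2 ± 4.82 CPM (SD, n = 4) in control and 25.7 ± 4.37 in the shifted arm at ZT0. At its low point, ZT12, it stood at 1.75 ± 0.383 CPM in control and 0.773 ± 0.117 after the shift. Cry1 (ENSMUSG00000020038, chromosome 10, 85131700 to 85185064) stood at 59.4 ± 3.63 CPM in control and 55.1 ± 6.02 in the shifted arm at ZT20, near its peak. At ZT0 Cry1 was at 30.6 ± 6.03 and 17.0 ± 5.50 CPM, a log2 difference of -0.85 (SE 0.27, adjusted p = 0.649 in edgeR). The fitted oscillation of Per1, a light-responsive and glucocorticoid-responsive repressor gene, had a log2 amplitude of 1.5 in control and 2.33 after the shift, a log2 ratio of 0.64 (0.18 to 1.14, permutation p = 0.0130, adjusted p = 0.221). Nr1d1, which encodes the repressor REV-ERBα, peaked at ZT 7.07 and ZT 7.12. The median amplitude over the 17 genes was 1.04-fold that of control (0.989 to 1.12, permutation p = 0.209). After adjustment over the 17 genes, no phase or amplitude difference passed the threshold.

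**Figure D2:**
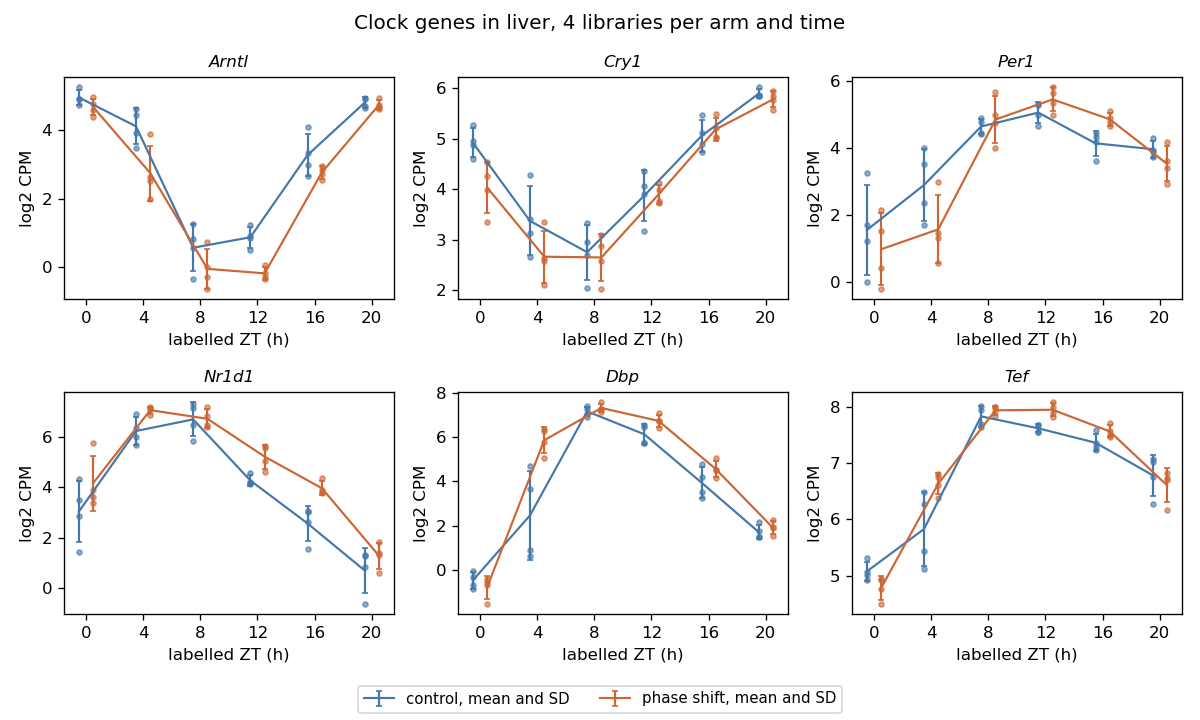
Log2 CPM of Arntl, Cry1, Per1, Nr1d1, Dbp and Tef against labelled ZT in hours. Points are libraries, lines join the means of 4 libraries, and bars are SD. Dbp at ZT4 stands at 61.8 CPM after the shift and 10.3 CPM in control, and Arntl at ZT12 at 0.773 and 1.75 CPM.

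The 17 clock genes together were also matched to the control curves, which gave each liver an internal time. The match used log2 CPM as it stood, so a difference of level or amplitude can move it as well as one of phase. The shifted livers at ZT12 matched a control clock time of -0.97 h relative to the label (SD 0.63, n = 4) and control livers one of 0.83 h (SD 0.61), a difference of -1.80 h (exact permutation p = 0.0286, adjusted p = 0.0858). At ZT16 the difference was -1.05 h (exact permutation p = 0.0286, adjusted p = 0.0858). At ZT0 and ZT4 the shifted livers read later than control, by 0.95 h and 1.98 h (exact permutation p = 0.0857 and adjusted p = 0.129 at each). At ZT8 and ZT20 the arms differed by 0 h and 0.09 h. Control livers themselves had a mean deviation from the label of 1.39 h at ZT8 and -0.97 h at ZT20. Because level and amplitude can enter, the differences at single times are not established as differences of clock phase. Averaged over all times the arms differed by 0.03 h (SE 0.22, permutation p = 0.929, n = 24 per arm). The 4 control livers at ZT4 had the widest spread, with an SD of 1.61 h. With 4 libraries per arm no exact p can fall under 0.0286, so no single time could pass after adjustment over 6 times unless several did.

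**Figure D3:**
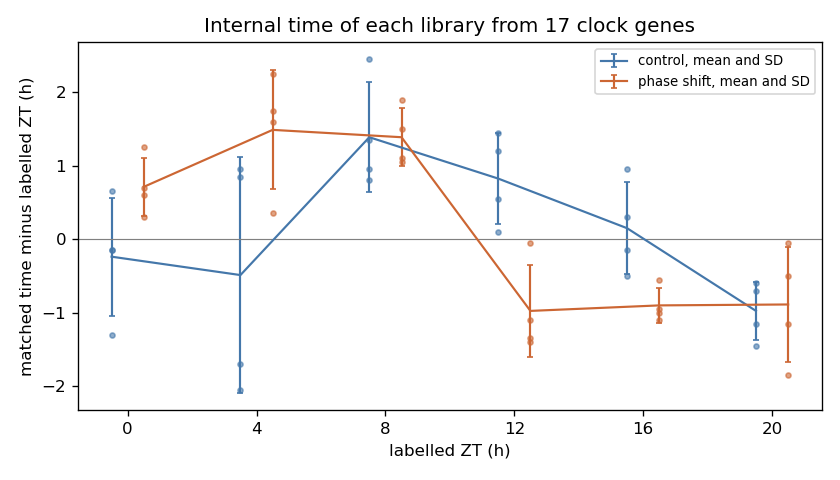
Internal time read from 17 clock genes minus the labelled ZT, in hours, against labelled ZT. Points are libraries, lines join the means of 4 libraries, and bars are SD. Shifted livers lie above control at ZT0 and ZT4 and below it at ZT12 and ZT16, and the mean difference over all times is 0.03 h.

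A second comparison asked which genes had another mean level over the day. Arntl was the gene with the smallest p, with a log2 difference of -0.67 (SE 0.13, adjusted p = 0.0634), and it lay below control in each of the 6 times. The activator list of the core clock holds 6 tested genes, all below control. None passed over all genes, whereas 3 fell when adjusted over the list alone, among them Arntl (adjusted p = 5.23e-05) and Clock (-0.18, adjusted p = 0.0243). The list median was -0.18 and camera gave an adjusted p of 3.94e-05, with adjusted p = 0.105 with an estimated correlation and an adjusted p of 0.0397 from the directional test of fry. Of 20 heat shock and chaperone genes, 15 lay below control, and 4 fell when adjusted over the list alone, none over all genes: Cacybp (-0.23), Hspb1 (-0.43), Hspa4l (-0.29) and Hsp90aa1 (-0.37). The list median was -0.09 (camera adjusted p = 0.000389, adjusted p = 0.546 with an estimated correlation). Cell cycle genes had a median of 0.62, with 7 of 19 higher over the list alone and 0 over all genes (adjusted p = 0.508 with an estimated correlation). The difference of the list means was 0.39, and 0.22 without phase shift ZT20 replicate 2, described below.

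Over all genes, edgeR called 0 of 14555 for the average difference, with 939 at an unadjusted p under 0.05. DESeq2 called 15 genes (7 higher, 8 lower) and limma called 1. Arntl passed in 8 of 57 alternatives, with adjusted p from 0.000896 to 0.192. Leaving out 1 library gave 3 genes without control ZT4 replicate 4, control ZT8 replicate 2 or control ZT12 replicate 1, and 2 without control ZT16 replicate 1 or phase shift ZT8 replicate 4. It gave 1 without control ZT0 replicate 2, control ZT8 replicate 4, control ZT20 replicate 3, or phase shift ZT0 replicate 1, ZT0 replicate 4, ZT4 replicate 1, ZT12 replicate 3, ZT16 replicate 4 or ZT20 replicate 4.

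At ZT8, 4 h before lights-off by the label, 4 genes for the disposal of amino acid nitrogen were lower in the shifted livers. Ass1, Asl and Arg1, consecutive enzymes of the urea cycle, fell by 0.84, 0.89 and 0.73 on the log2 scale (SE 0.18, 0.16 and 0.14), and Slc25a15, the mitochondrial ornithine carrier, by 0.67 (SE 0.12). Asl stood at 882 ± 161 CPM (SD, n = 4) in control and 476 ± 59.8 after the shift, and Arg1 at 1681 ± 227 and 1016 ± 95.1. The largest of the called changes with a mean log2 CPM of at least 1 was in Sdsl, a serine dehydratase-like gene, which fell by 1.3 (SE 0.28, adjusted p = 0.0423). Nnmt, which methylates nicotinamide and so consumes methyl groups, fell by 1.22 (SE 0.19, adjusted p = 0.00125), from 182 ± 27.6 to 78.5 ± 10.5 CPM.

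Of 16 members of the list for the urea cycle and arginine metabolism, these 4 fell over all genes, with adjusted p of 0.0105 for Asl and Slc25a15, 0.0144 for Arg1 and 0.0363 for Ass1. Adjusted over the list alone, 5 fell and 1 rose, and the list median was -0.24 (camera adjusted p = 0.00877, adjusted p = 0.348 with an estimated correlation). In the list for serine, glycine and one-carbon metabolism, 2 of 18 fell over all genes, Sdsl and Cth, the enzyme that makes cysteine from cystathionine (-0.96, adjusted p = 0.0423). Adjusted over the list alone 7 fell, among them Bhmt (-1.17), which remethylates homocysteine, and Sds (-0.98), the serine dehydratase. The list median was -0.25 (adjusted p = 0.279 with an estimated correlation). Glycolysis and glycogen genes had 6 of 16 lower over the list alone and 0 over all genes, with Eno1 at -0.39 and Tpi1 at -0.43 (adjusted p = 0.587 with an estimated correlation). The difference of that list's means was -0.16, -0.28 without control ZT8 replicate 2 and -0.05 without control ZT8 replicate 4. Arhgef19, a guanine nucleotide exchange factor, fell by 0.87 (adjusted p = 0.0132).

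Higher at ZT8 were 2 genes, Cyp2c23, a cytochrome P450 that oxidises arachidonic acid (0.64, SE 0.14), and Tmco4 (0.55, SE 0.12), both with an adjusted p of 0.0423. Fatty acid oxidation and PPARA target genes lay above control in 21 of 22 cases, with a median of 0.28. Of these 1 rose over the list alone and 0 over all genes, and that list had an adjusted p = 0.587 with an estimated correlation. Its difference of list means was 0.43, and 0.21 without control ZT8 replicate 2, a library with a high mitochondrial share. Stellate cell and fibroblast markers had a median of 0.48, with 6 of 13 higher over the list alone and 0 over all genes, among them Pdgfrb (0.66), Col1a1 (1.14), Col3a1 (0.85) and Col1a2 (0.81), and an adjusted p = 0.279 with an estimated correlation. Kupffer cell markers lay above control in 12 of 12 cases, with a median of 0.70 and 0 of 12 past the threshold over the list alone or all genes (adjusted p = 0.833 with an estimated correlation). They included Marco (1.67), Adgre1 (1.04), C1qc (0.79) and Lyz2 (0.71), and their difference of list means was 1.24, and 0.21 without control ZT8 replicate 2. Cell cycle genes had a median of 0.88 at ZT8, with 15 of 19 above control and 0 past the threshold over the list alone or all genes (camera adjusted p = 0.003, adjusted p = 0.833 with an estimated correlation), and Mki67 stood at 0.858 ± 0.398 CPM (SD, n = 4) in control and 3.41 ± 1.32 after the shift. Of 13 markers of periportal hepatocytes, the zone where urea synthesis is strongest, 2 fell over all genes, Arg1 and Ass1, and 4 over the list alone, with Sds and Gls2 (-0.45) added (adjusted p = 0.508 with an estimated correlation).

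In all, edgeR called 19 genes at ZT8, 2 higher and 17 lower, and 1702 had an unadjusted p under 0.05. DESeq2 called 74, and a fit without the high mitochondrial libraries called 7. The count was 5 without control replicate 2, 33 without control replicate 3, 8 without phase shift replicate 1, 1 without phase shift replicate 2, 2 without phase shift replicate 3 and 3 without phase shift replicate 4, and a fit to the 8 libraries of this time alone called 0. Nnmt passed in 16 of 17 alternatives (adjusted p from 2.38e-06 to 0.308), Slc25a15 in 14 (7.34e-05 to 0.814), Asl, Arg1 and Arhgef19 in 12 each, Ass1 in 8, Sdsl in 7, Cth and Tmco4 in 6 and Cyp2c23 in 4, and the highest adjusted p of each gene but Nnmt was 0.814.

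**Figure D4:**
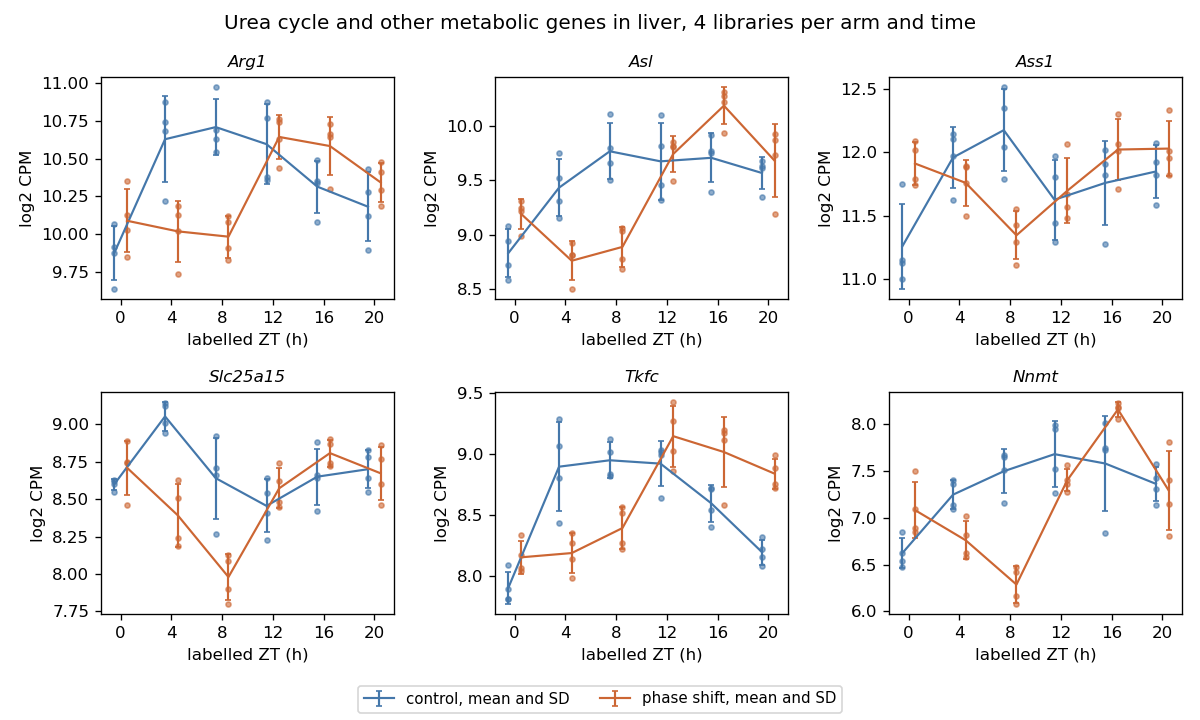
Log2 CPM of the urea cycle genes Arg1, Asl, Ass1 and Slc25a15, of Tkfc and of Nnmt against labelled ZT in hours. Points are libraries, lines join the means of 4 libraries, and bars are SD. At ZT8 shifted livers lie below control in each panel, and at ZT16 Asl stands at 1173 CPM after the shift and 842 CPM in control.

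At ZT4 the shifted livers had more of the clock output gene Dbp and less of Tkfc, a kinase of fructose breakdown, and of Slc25a15. Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203) rose by 2.59 on the log2 scale (SE 0.45, adjusted p = 0.0103), from 10.3 ± 11.4 CPM (SD, n = 4) in control to 61.8 ± 22.3. Inmt, a methyltransferase for indole amines and thioethers, rose by 0.86 (SE 0.17, adjusted p = 0.0230). Arntl, at -1.25 (SE 0.29), did not pass over all genes (adjusted p = 0.0642). The control livers at this time ran from 1.45 to 25.5 CPM of Dbp.

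Also called at ZT4 under the naming rule were Ngef (0.81), a guanine nucleotide exchange factor, and Gpr146 (0.79), a receptor with a role in blood cholesterol, both higher. Ccnf (cyclin F, -1.39), Tedc2 (-1.36), a centriole protein, Lgalsl (-0.99) and Rnf144b (-0.89), a ubiquitin ligase, fell. Of genes named at other times, Slc25a15 fell by 0.65 (adjusted p = 0.0156) and Tkfc by 0.74 (adjusted p = 0.0199). In the list of PAR bZIP factors and clock output, 1 of 17 rose over all genes, and over the list alone 5 rose and 3 fell. Tef stood at 0.71, Wee1 at 1.14 and Noct at -2.25. The list median was -0.22 and its mean 0.04, and fry's test for change in either direction gave an adjusted p of 0.0444, whereas camera, which asks for 1 direction, gave 0.784 (adjusted p = 0.955 with an estimated correlation). The difference of list means, 0.05, was -0.11, 0.16, 0.01 and 0.13 without control ZT4 replicates 1, 2, 3 and 4 in turn, and 0.01 without phase shift ZT4 replicate 4. The core clock activators had a median of -0.49, with 2 of 6 lower over the list alone and 0 over all genes, Arntl and Npas2 (-1.78), and an adjusted p = 0.291 with an estimated correlation. The difference of their means was -0.64, and -0.33 without the 3 libraries with a high mitochondrial share, without which that of the output list was -0.08.

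Glucocorticoid target genes had a median of -0.65 at ZT4. Over the list alone 6 of 16 fell, among them Tsc22d3 (-1.36), Errfi1 (-1.17), Tat (-0.83) and Ddit4 (-1.30), and 0 over all genes (camera adjusted p = 5.07e-05, adjusted p = 0.279 with an estimated correlation). Of 11 gluconeogenesis genes 3 fell over the list alone and 0 over all genes, G6pc, the last enzyme of glucose release (-1.71), Tat and Slc37a4 (-0.54), and the list had an adjusted p = 0.395 with an estimated correlation. Its difference of list means was -0.45, and -0.14 without the 3 libraries with a high mitochondrial share, where G6pc at ZT4 stood at -0.77 (adjusted p = 0.736). Stellate cell and fibroblast markers had a median of 0.42, with 3 of 13 higher over the list alone and 0 over all genes, Colec11 (0.53), Reln (0.68) and Hhip (0.75), and an adjusted p = 0.395 with an estimated correlation. The difference of their means was 0.34, and 0.16 without these 3 libraries.

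At ZT4 edgeR called 17 genes, 4 higher and 13 lower, and 1341 had an unadjusted p under 0.05. DESeq2 called 111 and limma 33. The fit to the 8 libraries of this time alone called 0, the fit without the libraries with a high mitochondrial share (control replicate 1, phase shift replicates 2 and 3) called 1, and that with the share as a covariate called 58. The count was 0 without control replicate 2, 3 without control replicate 3, 45 without control replicate 4, 62 without phase shift replicate 1, 10 without phase shift replicate 2, 6 without phase shift replicate 3 and 5 without phase shift replicate 4. Dbp passed in 14 of 17 alternatives (adjusted p from 2.07e-05 to 0.559) and Rnf144b in 14 (0.000316 to 0.202). Both missed the threshold without control replicate 2 (adjusted p = 0.0683). Without the high mitochondrial libraries, Dbp at ZT4 stood at 1.74 (adjusted p = 0.177).

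At ZT20 genes for cell division were high in 1 shifted liver. Phase shift ZT20 replicate 2 held 84 CPM of Mki67, a marker of cycling cells, 71.9 CPM of Top2a, which untangles DNA, and 53.9 CPM of Cdk1, the kinase that starts mitosis. The highest levels in the other 47 libraries were 5.39, 3.69 and 3.31 CPM. Of 19 cell cycle genes tested, 9 rose over all genes and 17 over the list alone, with Cdc20 at 5.46 (SE 1.01), Ccnb2 at 4.44, Mki67 at 4.18 and Ccna2 at 4.41, each with an adjusted p of 0.0183 (list median 2.64, adjusted p = 0.342 with an estimated correlation). The difference of list means was 1.24, and 0.22 without that liver. It also had the lowest mean of the 48 for male-biased liver genes (6.86, against 8.26 to 8.98 in the other 3 of its group) and the highest for female-biased liver genes (3.35, against 0.197 to 1.87). Outside cell division, Tkfc rose by 0.65 (SE 0.14, adjusted p = 0.0281), from 293 ± 21.3 CPM (SD, n = 4) to 459 ± 39.8, and Nbeal1 fell by 0.53 (SE 0.13, adjusted p = 0.0452). Fatty acid synthesis genes had a median of 0.43 and 16 of 17 above control, with Fasn at 1.00, Acaca at 0.54, Elovl6 at 0.94 and Me1 at 0.46, none past the threshold over the list alone or all genes (camera adjusted p = 0.00249, adjusted p = 0.684 with an estimated correlation). Their difference of list means was 0.46, and 0.25 without phase shift ZT20 replicate 2.

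At this time edgeR called 43 genes, 42 higher and 1 lower, and 1067 had an unadjusted p under 0.05. The count was 0 without phase shift replicate 2, and 0 without each of control replicates 1, 2, 3 and 4. It was 92 without phase shift replicate 1, 94 without phase shift replicate 3 and 81 without phase shift replicate 4. Limma called 0 and DESeq2 60. Tkfc passed in 7 of 17 alternatives (0.00396 to 1) and Nbeal1 in 4 (0.0193 to 1).

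At ZT16 no single gene passed in edgeR, and cholesterol synthesis had the widest median of the 39 lists. All 23 genes of cholesterol synthesis lay below control, with a median of -0.73. Of these 5 fell over the list alone and 0 over all genes, among them Hmgcs1 (-1.39), Sc5d (-0.74) and Pmvk (-0.92), and camera gave an adjusted p of 2.54e-17 (adjusted p = 0.342 with an estimated correlation). Hmgcs1 stood at 340 ± 132 CPM (SD, n = 4) in control and 130 ± 40.3 after the shift. Fatty acid synthesis genes lay below control in 16 of 17 cases, with a median of -0.35, Pnpla3 at -2.35, Acss2 at -0.78, Me1 at -0.46 and Fads1 at -0.30, and 0 past the threshold over the list alone or all genes (adjusted p = 0.395 with an estimated correlation).

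Among gluconeogenesis genes at ZT16, 3 of 11 rose over the list alone and 0 over all genes, Pck1, which commits carbon to glucose (1.80, SE 0.44), Foxo1 (0.55) and Got1 (1.02), with adjusted p = 0.279 with an estimated correlation. The difference of list means was 0.33, and 0.12 without phase shift ZT16 replicate 2, where Pck1 had an adjusted p of 1. Pck1 stood at 784 ± 136 CPM (SD, n = 4) in control and 2736 ± 1855 after the shift. Glucocorticoid target genes had a median of 0.64, and 4 of 16 rose over the list alone and 0 over all genes, Angptl4 (1.54), Lpin1 (1.74), Fkbp5 (1.14) and Zbtb16 (1.80), with adjusted p = 0.342 with an estimated correlation. Their difference of list means was 0.58, and 0.28 without phase shift ZT16 replicate 2. The clock repressors had a median of 0.37, and 2 of 10 rose over the list alone and 0 over all genes, Nr1d1 (1.33) and Ciart (1.25), with adjusted p = 0.279 with an estimated correlation. Acute phase genes lay above control in 21 of 22 cases (median 0.29), with Lbp (0.70) higher over the list alone and 0 over all genes, and adjusted p = 0.279 with an estimated correlation. The difference of their means was 0.32, and 0.19 without phase shift ZT16 replicate 4. In edgeR 0 genes passed at ZT16, 643 had an unadjusted p under 0.05, DESeq2 called 10 (7 higher, 3 lower), limma called 0, and the fit to the 8 libraries of this time alone called 13 (7 higher, 6 lower).

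At ZT12, cholesterol synthesis genes lay below control in 22 of 23 cases (median -0.48), with Hmgcs1 at -1.27, Mvd at -1.18, Msmo1 at -0.80 and Lss at -0.71, and 0 past the threshold over the list alone or all genes (adjusted p = 0.833 with an estimated correlation). The difference of the list means was -0.40, -0.10 without control ZT12 replicate 4 and -0.25 without phase shift ZT12 replicate 2. Stellate cell and fibroblast markers had a median of -0.35, and Hhip (-0.85), Rgs5 (-0.54) and Pdgfrb (-0.49), 3 of 13, fell over the list alone and 0 over all genes (adjusted p = 0.395 with an estimated correlation). Acute phase genes had a median of -0.25, and 1 of 22, Saa4 (-0.75), fell over the list alone and 0 over all genes (adjusted p = 0.395 with an estimated correlation). At ZT0, transcripts of the mitochondrial genome lay above control in 15 of 15 cases (median 0.88), and 12 rose over the list alone and 0 over all genes, with mt-Nd3 at 1.94, mt-Atp8 at 1.29, mt-Nd6 at 0.94 and mt-Nd4 at 0.88 (adjusted p = 0.684 with an estimated correlation). Without phase shift ZT0 replicate 1 the difference of list means was 0.08, against 0.64 with it and -0.17 without both shifted libraries with a high mitochondrial share, and the value of mt-Nd3 at ZT0 was -0.17, and without the libraries with a high mitochondrial share mt-Nd4 at ZT0 stood at -0.02.

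Also at ZT0, sinusoidal endothelial markers lay below control in 12 of 12 cases (median -0.62), with Lyve1 at -1.75, Stab2 at -0.75, Stab1 at -0.71 and Pecam1 at -0.57, and 0 past the threshold over the list alone or all genes (adjusted p = 0.739 with an estimated correlation). The shifted group at ZT0 holds 2 libraries with a high mitochondrial share, 19.9% and 9.88%, and the difference of list means was -1.05, -0.49 without phase shift ZT0 replicate 1 and 0.02 without both. Fatty acid oxidation and PPARA target genes lay below control in 20 of 22 cases (median -0.26), with Vnn1 at -0.92, Acadm at -0.27 and Acadl at -0.24, and cholesterol synthesis genes above it in 21 of 23 (median 0.29), with Mvd at 1.05, Mvk at 0.64, Nsdhl at 0.57 and Dhcr7 at 0.55. In both lists 0 genes passed over the list alone or all genes (adjusted p = 0.587 and adjusted p = 0.833 with an estimated correlation). The oxidation list had a difference of means of -0.43, and -0.28 without phase shift ZT0 replicate 1, and the cholesterol list one of 0.35, and 0.16 without control ZT0 replicate 3. In edgeR 0 genes passed at ZT0 and 1072 had an unadjusted p under 0.05, and at ZT12 0 passed and 725 had an unadjusted p under 0.05. DESeq2 and limma called 0 at both times.

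A further comparison asked which genes cycle over the day in each arm. The largest control amplitudes outside the core clock were those of Dbp, at 3.48 log2 units with a peak at ZT 10.3, Mup10, a major urinary protein (3.26, ZT 3.01), Rgs16, a regulator of G protein signalling (2.64, ZT 8.35), Pitx3 (2.17, ZT 22.4) and Usp2, a deubiquitinase (2.12, ZT 12.5). After the shift they peaked at ZT 9.42, 21.4, 8.63, 21.9 and 12.8. These values are from the edgeR fit to counts. The clock gene peaks given earlier are from least squares on log2 CPM, which for Dbp gave ZT 10.8 and ZT 9.91. Usp2 moved from 3.47 ± 1.70 CPM (SD, n = 4) at ZT0 to 77.0 ± 3.34 at ZT12 in control, and from 2.92 ± 1.18 to 82.3 ± 13.7 after the shift. The value of Mup10 rests on single livers, with 248 ± 489 CPM in control at ZT0, and without control ZT0 replicate 1 its amplitude was 2.09 (Mup10 amplitude in control, adjusted p = 0.0312). It passed in 53 of 55 alternatives, with adjusted p from 0.00621 to 0.699, and the other 4 genes passed in 55 of 55.

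In all, 3975 genes were rhythmic in control and 4106 after the shift, of 14555 tested in edgeR, and 2066 in both, where 1121 are expected from independent lists. Peak-to-trough differences exceeded 2-fold in 1067 and 1362 of the rhythmic genes. Among the 2066 genes rhythmic in both arms, the median difference of peak time was -0.10 h, with quartiles at -1.27 and 1.16 h, and 52.1% peaked earlier after the shift. In the 564 of these with more than 2-fold differences in both arms the median was 0.19 h. A call in 1 arm and not in the other was not read as a difference.

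The last comparison tested the daily time course itself for a difference between arms. Tkfc and Asl, of fructose breakdown and the urea cycle, had the smallest p, followed by the little-known genes Gm47465 and E030018B13Rik and then by Arg1. Tkfc peaked at ZT 9.43 in control and ZT 14.9 after the shift, 5.42 h later (adjusted p = 0.000263), Asl at ZT 12.2 and ZT 16.4, 4.23 h later (adjusted p = 0.00484), and Arg1 at ZT 9.15 and ZT 15.3, 6.19 h later (adjusted p = 0.0164). Khk, the kinase that starts fructose breakdown, had an amplitude of 0.34 in control, with a peak at ZT 8.95, and 0.18 after the shift, where it was not called rhythmic (adjusted p = 0.0907, adjusted p of the difference 0.0220). The glycolytic gene Eno1 had peaks at ZT 11.0 and ZT 17.9 (adjusted p = 0.0276).

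Tkfc (ENSMUSG00000034371) lies on chromosome 19, 10592200 to 10604258, Asl (ENSMUSG00000025533) on chromosome 5, 130011258 to 130029247, and Arg1 (ENSMUSG00000019987) on chromosome 10, 24915221 to 24927484. Arg1 stood at 1602 ± 287 CPM (SD, n = 4) in control and 1046 ± 140 after the shift at ZT4, and at 1279 ± 146 and 1543 ± 191 at ZT16. Asl stood at 842 ± 125 and 1173 ± 131 CPM at ZT16, and its log2 amplitude was 0.36 in control and 0.71 after the shift. Eif4a2, an RNA helicase of translation initiation, had an amplitude of 0.06 in control, where it was not called rhythmic (adjusted p = 0.321), and 0.27 after the shift with a peak at ZT 6.21 (adjusted p of the difference 0.0164). Earlier fitted peaks after the shift were found in Hsd17b11, a lipid droplet dehydrogenase (-7.10 h), Tm6sf2, which acts in lipoprotein secretion (-8.60 h), and Gramd1c, a sterol transfer protein (-5.03 h), with adjusted p of 0.0276, 0.0289 and 0.0316. Gsdmd, a pore-forming protein of inflammatory cell death, had an amplitude of 0.44 in control and 0.11 after the shift, where it was not called rhythmic (adjusted p = 0.347, adjusted p of the difference 0.0276).

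By list, 3 of 16 genes of the urea cycle and arginine metabolism differed in time course over all genes, Asl, Arg1 and Slc25a15 (adjusted p = 0.0467), and 9 when adjusted over the list alone, with Ass1 among them (peaks at ZT 8.84 and ZT 19.8). In gluconeogenesis 6 of 11 differed over the list alone and 0 over all genes, including Slc37a4, Got1, Gpt and G6pc. In glycolysis and glycogen 5 of 16 differed over the list alone and 1, Eno1, over all genes, with Tpi1 peaking at ZT 11.0 and ZT 19.8 and Pklr at ZT 11.0 and ZT 14.2. In serine, glycine and one-carbon metabolism 6 of 18 differed over the list alone, with Mat1a, Bhmt and Sds, and 1, Sdsl, over all genes. Periportal markers gave 6 of 13 over the list alone, with Etnppl, and 1, Arg1, over all genes. Fatty acid oxidation gave 2 of 22 over the list alone, with Vnn1 among them, and 1 over all genes, with Hadhb and Cpt1a past neither. Cholesterol synthesis gave 0 of 23 by either count, with Mvk, Mvd, Nsdhl and Acat2 each at an adjusted p over the list alone of 0.0667.

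Of 14555 genes, 27 differed in time course in edgeR and 2813 had an unadjusted p under 0.05. Of the 27, 20 were rhythmic in both arms, and 13 of these had a later and 7 an earlier fitted peak after the shift, with 2 more than 10 h apart, where the sign is arbitrary. The test with 5 degrees of freedom called 20 genes (1600 at an unadjusted p under 0.05), of which 13 were among the 27. Without the high mitochondrial libraries the 27 genes all had an unadjusted p under 0.05 and 13 of them were called. Tkfc, Asl, Arg1 and Eif4a2 passed in 55 of 55 alternatives, with the highest adjusted p at 0.00301, 0.0154, 0.0498 and 0.0498. Eno1 passed in 50, Khk and Hsd17b11 in 49, Gsdmd in 48, Tm6sf2 in 47 and Gramd1c in 45. The count was 6 without phase shift ZT8 replicate 1, 2 or 4, 8 without phase shift ZT20 replicate 3, 10 without control ZT20 replicate 1, and 11 without control ZT8 replicate 2 or phase shift ZT8 replicate 3. It was 12 without control ZT0 replicate 3 or control ZT4 replicate 2, 13 without control ZT12 replicate 2 or phase shift ZT12 replicate 1, 14 without control ZT16 replicate 3, and 15 without control ZT0 replicate 2 or control ZT4 replicate 4. It was 16 without control ZT0 replicate 4, control ZT16 replicate 1 or 2, phase shift ZT16 replicate 4 or phase shift ZT20 replicate 1, 17 without control ZT20 replicate 3, and 43 without control ZT12 replicate 3.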

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

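Of the tests of explanations below, 1 prediction, that of blood or immune cells in phase shift ZT20 replicate 2, was written before its result was seen, and the others were chosen after the result was seen. Tkfc, Asl and Arg1 are among 27 genes that stood out because the test of daily time courses separates the arms for them. Fitted peaks differed by 5.42 h for Tkfc, 4.23 h for Asl, 6.19 h for Arg1, 6.86 h for Eno1, -7.1 h for Hsd17b11, -8.6 h for Tm6sf2 and -5.03 h for Gramd1c, all rhythmic in both arms. They differed by 6.16 h for Eif4a2, not called rhythmic in control, and by 9.99 h for Khk and -6.3 h for Gsdmd, not called rhythmic after the shift. For these 3 a peak in 1 arm is itself not established. For the others the test takes peak time and amplitude together, and peak time alone was not tested. Arhgef19, also among the 27, passed with a peak difference of -0.18 h and log2 amplitudes of 0.24 in control and 0.76 after the shift. Of 100 splits of the livers into mixed arms, the real one alone gave as many genes (1 of 100, real 27, highest other 3), so chance can be excluded for this count. At ZT8 the real grouping alone gave as many genes (1 of 35 splits, real 19, highest other 2). With 35 splits the share cannot fall under 0.0286, and 6 times were tested, so chance is not excluded there.

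For the urea cycle and amino acid genes, 2 technical explanations were tested. If libraries with a high mitochondrial share made the difference at ZT8, the 17 lower genes would lose it without them. Their median log2 fold change was -0.63 without these libraries and -0.76 with them, and 6 of the 17 were called again. At ZT8 the only such library is control replicate 2, and the 17 genes were chosen with all libraries in the fit. A median that stays low is favoured by that choice, so the part of this library is left open. For the daily time courses, the 27 genes had a median size of the difference of 0.52 log2 units with all libraries, 0.47 without these libraries and 0.49 with the share as a covariate. Of the 27, 13 were called again without these libraries and 26 with the covariate. For those 13 this argues against these libraries as the whole source. The 27 genes were chosen with these libraries in the fit, and the size was measured without its direction. The part of these libraries in the other genes is therefore left open. If less periportal tissue had been sampled, the other 9 periportal markers would be lower too. Their median at ZT8 was -0.1 (range -0.4 to 0.47), with 7 of 9 below 0, and pericentral markers had a median of 0.21 (camera adjusted p = 0.0408, adjusted p = 0.684 with an estimated correlation). A part of the difference from less periportal tissue is therefore left open. A change of metabolic gene timing remains a hypothesis that may be tested on food intake, which was not used here.

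Genes of cell division stood out in phase shift ZT20 replicate 2, with a list mean of 4.971 log2 CPM against 0.568 to 1.179 in the other 3 libraries of its group. The same liver had the lowest mean of the 48 for male-biased liver genes (6.856, against 8.262 to 8.981 in its group), unfolded protein response (5.641, against 6.049 to 6.49), bile acid genes (7.362, against 7.834 to 7.904) and insulin, IGF and growth hormone signalling (5.22, against 5.644 to 6.009). It had the highest for female-biased liver genes (3.35, against 0.197 to 1.874), NRF2 and antioxidant genes (8.002, against 7.24 to 7.345) and fatty acid synthesis (9.274, against 8.296 to 8.571). The 42 genes called higher had a median log2 fold change of 3.77 with all libraries, 0.3 without that library and 3.61 to 4.16 without any 1 of the other 7. If blood or immune cells were the cause, 1 of their 3 marker means would lie above the others by over 2 SD, and if not, all 3 would lie within 2 SD. The highest was 1.1 SD (erythroid), with neutrophil markers at -0.89 SD and lymphocyte markers at -2.59 SD, so neither prediction was met. No list lay above the others by over 2 SD, and the 1 beyond 2 SD lay below, opposite to what more lymphocytes would give. The explanation as a whole is left open. Of the 35 splits of the 8 livers at ZT20, 10 gave as many genes (real 43, highest other 92, median of the others 33), so chance cannot be excluded, and so many calls point to a structure of the samples. A median of 0.3 without it is consistent with replicate 2 as the source of nearly the whole difference, and why genes of cell division were high in that liver was not tested.

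Kupffer and sinusoidal endothelial markers stood out as low in libraries with a high mitochondrial share. The match was not complete. Within groups the Kupffer and endothelial lists each had a correlation of -0.97 with the first principal component of log2 CPM, which held 23.56% of the variance. With the share it was -0.89 and -0.88. Leaving out libraries by their share therefore does not remove the whole pattern. Control ZT20 replicate 1, at 12.14%, had Kupffer and endothelial means of 4.236 and 4.656, against 4.458 to 5.209 and 4.888 to 5.12 in its group. Phase shift ZT16 replicate 1, at 7.523%, had lower means of 3.433 and 3.67, against 4.685 to 5.291 and 4.956 to 5.194. A loss of every kind of non-parenchymal cell would lower stellate cell markers as well, but their slope was 0 (SE 0.1) per doubling of the share, that of lymphocyte markers -0.08 (SE 0.13) and that of cholangiocyte markers -0.4 (SE 0.18). Neutrophil markers, with 5 genes tested, had a slope of -0.64, so a loss that reaches some other kinds of cell is left open. A loss of long transcripts would lower other genes of like length, but the 24 marker genes had a median slope of -2.36 (range -3.49 to -1.39) against 0.1 for genes of like length, a difference of -2.45. Over 14525 nuclear genes the slope did fall with gene length (Spearman correlation -0.344), so longer genes tended lower as the share rose. Length alone does not give the size of the marker slopes, but an effect of length in these libraries is not excluded. The source of the pattern is open, and sampling or dissociation of Kupffer and endothelial cells was not tested.

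Single libraries far from the other 3 of their group were found in 15 of 168 sets tested, where chance gives about 1 in 20, or 8.4. By mitochondrial share these were control ZT4 replicate 1, at 11.49% against 7.353 to 8.016, and control ZT20 replicate 1, at 12.14% against 7.046 to 7.2. Control ZT4 replicate 1 also had 5.282% of its counts on Alb, the albumin gene, against 7.562 to 7.822, and a Kupffer marker mean of 2.933 against 4.423 to 4.546. On the first principal component, control ZT8 replicate 2 lay at 110.27 against -16.95 to -1.91, phase shift ZT12 replicate 4 at -21.15 against 2.96 to 6.96, and phase shift ZT16 replicate 1 at 16.75 against -18.29 to -13.73. Endothelial marker means were 5.171 in phase shift ZT12 replicate 4 against 4.191 to 4.319, and 3.67 in phase shift ZT16 replicate 1 against 4.956 to 5.194. The cell cycle mean of phase shift ZT8 replicate 4 was 1.106 against 1.349 to 1.362. Log2 CPM of Cry1 was 6.02 in control ZT20 replicate 3 against 5.84 to 5.87, that of Asl 9.49 in phase shift ZT12 replicate 4 against 9.81 to 9.85, and that of Mki67 2.46 in phase shift ZT8 replicate 2 against 1.48 to 1.56. Phase shift ZT12 replicate 2 had 16118432 counts against 17041273 to 17174215.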

How the results depend on the processing

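The 2 settings that treat the mitochondrial share were chosen after the result was seen, and the others before. Counts of rhythmic genes ranged from 2795 to 4690 in control and from 3089 to 4846 after the shift over the settings run, and which arm held more turned with the covariate (4690 and 4644). With 1 library left out they were 3035 to 4401 and 3727 to 4631. ZT0 and ZT12 gave 0 genes throughout. At ZT4 (17 genes) limma gave 33, DESeq2 111, the 8 libraries alone 0, no high mitochondrial libraries 1, the share as a covariate 58, and leaving out 1 library 0 to 62. At ZT8 (19) no filter gave 9, the replicate block 12, DESeq2 74, the 8 libraries alone 0, no high mitochondrial libraries 7, the covariate 29, and leaving out 1 library 1 to 33. At ZT16 (0) DESeq2 gave 10 and the 8 libraries alone 13. At ZT20 (43) no filter gave 25, the stricter filter 16, the replicate block, limma, the 8 libraries alone and no high mitochondrial libraries 0 each, the covariate 129, and leaving out 1 library 0 to 94. For the average (0) the replicate block and limma gave 1 each, DESeq2 15, the covariate 3, and leaving out 1 library 0 to 3. Differential rhythmicity (27) gave 45 with no filter, 15 with the replicate block, 72 with the covariate and 6 to 43 with 1 library left out. Replicate numbers do not pair the livers, so the block counts are given as values.

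The clock gene phase difference of -0.47 h was -0.23 h without the high mitochondrial libraries, and the amplitude log2 ratio of 0.06 was -0.01 without them and -0.08 for activators alone. The 74 gene list calls became 0 with an estimated correlation. Reversed were mt-Nd3 at ZT0, at -0.962 without the high mitochondrial libraries, -0.174 without phase shift ZT0 replicate 1 and up to 2.348 with 1 library left out, and mt-Nd4 at ZT0, at -0.021 without the high mitochondrial libraries. Fewer libraries enter fits to the 8 libraries alone; elsewhere the cause was not tested. Of values of named genes at single times under other settings, 1048 stayed, 28 grew, 71 weakened and 2 reversed, and with 1 library left out 1392 stayed, 17 grew, 110 weakened and 1 reversed.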

Other observations

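The tests of daily list profiles, of metabolic against clock lists and of list means without 1 library were chosen after the result was seen. Bile acid synthesis and transport genes, which turn cholesterol into bile, lay below control in 13 of 16 cases at ZT20, with a median of -0.21 and 0 of 16 past the threshold over the list alone or all genes (camera adjusted p = 0.00134, adjusted p = 0.534 with an estimated correlation). Their difference of list means was -0.24, and -0.11 without phase shift ZT20 replicate 2. Ribosome biogenesis genes, which feed protein synthesis, lay above control in 18 of 21 cases at ZT20, with a median of 0.21 and 0 of 21 past the threshold by either count (camera adjusted p = 0.000736, adjusted p = 0.631 with an estimated correlation). Sphingolipid metabolism genes, of interest because the labels name sphingomyelin, had an average difference with a median of 0 and 0 of 23 past the threshold (camera adjusted p = 0.849, adjusted p = 0.955 with an estimated correlation).

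A hypothesis was that gene lists outside the clock have another daily profile after the shift. The adjusted p takes peak time and amplitude together, and the intervals are those of the peak time difference. Of 36 such lists 5 passed an adjusted p of 0.05, and 0 of 3 clock lists did (adjusted p of 0.639, 0.328 and 0.189). Gluconeogenesis peaked at ZT 9.98 in control and ZT 14.2 after the shift, 4.18 h later (1.74 to 6.84, permutation adjusted p = 0.0354), and glycolysis and glycogen 2.8 h later (1.11 to 4.42, adjusted p = 0.0354). Serine, glycine and one-carbon metabolism differed by -11.5 h (-15.6 to -6.04, adjusted p = 0.0354), where earlier and later are nearly the same, and fatty acid oxidation by -8.08 h (-16.0 to 0.4, adjusted p = 0.0433). Glucocorticoid target genes passed with an amplitude of 0.22 SD units in control and 0.69 after the shift (adjusted p = 0.0433). Phase shift ZT16 replicate 2 had a glucocorticoid target mean of 6.279 log2 CPM, against 4.831 to 5.313 in the rest of its group. Its gluconeogenesis mean was 8.626, against 7.641 to 7.947. Profiles were not refitted without that liver, so its part in both is left open. The urea cycle list, 5.41 h later (2.8 to 8.5), had an adjusted p of 0.0695. Within groups the fatty acid oxidation list had a slope of -0.49 log2 units per doubling of the mitochondrial share, gluconeogenesis -0.33, glucocorticoid targets -0.29, serine -0.18 and glycolysis -0.10. The shifted libraries with a high share sit at ZT0 and ZT4, so an effect of that share on these 5 profiles is left open.

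A second hypothesis was that metabolic lists moved later than clock lists. The mean phase difference of 4 metabolic lists minus that of 3 clock lists was 0.36 h (-0.2 to 6.53, permutation p = 0.896). The serine list lies close to a difference of 12 h, where its sign is arbitrary, so this mean could not be read and says nothing for or against the hypothesis.

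Livers were also split at random into mixed groups for the other counts. At ZT4, 2 of 35 splits gave as many genes (real 17, highest other 21), so chance cannot be excluded. The split with 21 puts the 3 libraries with a high mitochondrial share together, and the real split gave 1 gene without them and 58 with the share as a covariate. At ZT0 the real count is 0, so 35 of 35 splits gave as many by construction (edgeR, 1072 at an unadjusted p under 0.05, DESeq2 and limma 0), and the highest other, 46, puts the 2 shifted libraries with a high share together, which points to a structure of the samples. At ZT12 and at ZT16 the real count in edgeR is also 0, and 35 of 35 splits gave as many (725 and 643 at an unadjusted p under 0.05, DESeq2 0 and 10, limma 0 and 0), with a highest other of 0, and for the average 100 of 100 did (939 at an unadjusted p under 0.05, DESeq2 15, limma 1), with a highest other of 0. Against a count of 0 the splits say nothing about chance. For rhythmic genes the real order of times alone gave as many, in 1 of 100 splits in control (real 3975, highest other 3) and 1 of 100 after the shift (real 4106, highest other 201). Chance can be excluded there as far as 100 splits allow.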
